A study of Komagataella phaffii with 6 samples.

How the data were processed

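Gene expression was measured in 6 RNA samples of Komagataella phaffii strain X-33, a methylotrophic yeast (formerly Pichia pastoris) that can live on methanol as its carbon source. Per the labels' protocols, cells were grown for 40 h in 100 ml of a glycerol medium, collected, and moved for 18 h into a methanol medium that either held ammonium sulfate or held no nitrogen source. Libraries were made from 300 ng of total RNA with a QuantSeq forward kit, which primes on the poly(A) tail and reads one fragment near the 3' end of each transcript. The labels number 3 replicates in each of the 2 groups. They do not say whether these were separate cultures, so the spread between these samples, on which p-values here rest, may be partly technical. For single genes that spread was mostly pooled over all genes.

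The authors deposited raw counts of reads per gene, in 1 table of the whole series, with no normalization. Trimmomatic, HISAT2 and featureCounts are named per the submitters' processing notes, and their versions and settings, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table's 5040 locus tags, and their start and end positions, all match the RefSeq annotation of assembly ASM2700v1 of strain GS115. All 5040 gene lengths are multiples of 3, so the deposited counts were made over coding sequence without untranslated regions. Fragments that lie wholly in a 3' untranslated region would therefore not be in the counts. The labels mention no molecular identifiers, so counting intervals cover counting error only.

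The table and the reference give locus tags but no gene symbols or product descriptions. Of the 38 gene lists fixed before the data were examined, 36 had no recognisable member, 1 (glycolysis and gluconeogenesis) had 1, and only the list of methanol utilization genes had at least 4 and was tested. Its 9 members, together with MXR1 and TDH3, had been written down by locus tag before the data were examined, from prior knowledge of the K. phaffii literature. They are not taken from a source used here, which pairs no locus tag with a name. The table's gene structures do not contradict these identities: AOX1 and AOX2 have equal coding lengths of 1992 bp, DAS1 and DAS2 have equal lengths of 2124 bp, and FLD1 is the only one of the 11 genes with 2 coding exons. The names were not checked against sequence. The rule for named genes, also fixed in advance, took these genes except FGH1 and DAK2 whatever their result. It also took the 8 largest rises and falls with a named function. FGH1 and DAK2 were fixed as members of the list, and are given with the others. No other gene had a named function, so only 2 locus tags per direction are printed, ranked in the same way (adjusted p under 0.05, mean of at least 10 CPM, groups that do not overlap). The fixed ammonium permeases, general amino acid permease, glutamine and glutamate enzymes, urea amidolyase, ATG8, PEP4 and PRB1 could not be matched to a locus tag and are not analysed here.

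Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr (minimum count 10), which left 3330 genes. Library sizes were scaled by TMM, and the group difference was tested with the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05. Fold changes are log2, without nitrogen minus with nitrogen. The standard error (SE) of a fold change was taken as its size divided by the square root of F. The estimated prior degrees of freedom were 985, so nearly all of the spread assigned to a gene came from the trend over all genes. A gene's SE and p-value therefore say little about the spread of its own libraries. The list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. CPM are read counts as a share of the TMM-scaled library size, in the usual unit of that name. Single values per library were compared by exact permutation tests, two-sided, for which 3 samples against 3 cannot give a p below 0.1. Shares of counts carry exact 95% Clopper-Pearson intervals.

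The test was checked on simulated counts with the real means and library sizes, in 5 runs of 200 changed genes. Gene spreads were edgeR's own estimates from these data, and genes varied independently. The test recovered 34.0% of 1.5-fold changes, 69.0% of 2-fold, 92.7% of 3-fold and 99.1% of 4-fold changes among about 3187 genes tested. In these runs 3.38% of its calls were false. Because the spreads came from the model under test, these shares need not hold for the real calls. For the methanol list, a simulated shift of -0.3 (log2) was called in 100% of 40 runs and no shift in 0%; genes in that simulation varied independently. Replicate libraries differed by more than sampling noise in all 6 pairs (chi-square per degree of freedom 1.82 to 2.70), so none was counted as a duplicate. This does not show that the replicates came from separate cultures.

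Alternatives fixed before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, each library left out in turn, the replicate number as a block, and size thresholds. The dispersion step ran with edgeR's default of this version. That setting was taken as the main one after a first fit with the other setting (legacy = FALSE) had been seen; it called 220 genes against 211, and FLD1 passed under it but not under the default. Added after seeing the data were thinning of all libraries to the smallest total, 2 other settings of edgeR's dispersion step, summed paralogs, and another total for the share of counts.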

Results

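The data were 3' end counts from 3 libraries of K. phaffii X-33 kept on methanol with ammonium sulfate and 3 libraries kept on methanol without a nitrogen source, all sampled at 18 h. The libraries were shallow. Those with nitrogen held 435003, 302395 and 320915 counts on 5040 genes, and those without nitrogen held 302837, 395803 and 127303. The median tested gene had 13 counts in replicate 3 without nitrogen, against 29 to 45 in the other libraries. On the first principal component, which held 38.6% of the variance, the libraries with nitrogen lay between -12.2 and -9.13 and those without nitrogen at 1.78, 3.43 and 26.9, the last being the shallow replicate 3.

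The comparison asked which transcripts differ when cells grown on glycerol are moved into methanol medium without nitrogen rather than with it. Of 3330 genes tested, 122 were higher and 89 lower without nitrogen, 6.34% of the genes. In simulated data with the real library sizes and edgeR's estimated spreads, 34.0% of 1.5-fold changes were called, so many smaller changes could have been missed. At least 2-fold changes were found for 40 of the higher and 24 of the lower genes, and at least 4-fold changes for 7 and 1. The 122 higher genes took 7.26% ± 0.192 of all counts with nitrogen and 12.8% ± 0.134 without (SD, n = 3 each), and the 89 lower genes took 10.8% ± 0.190 and 7.35% ± 0.243. These shares describe genes chosen for their change. The median fold change of all tested genes was near 0 under every scaling tried. Most of these scalings centre the bulk of genes, and counts are relative. The median therefore does not show whether the total amount of transcript changed.

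The largest rise was that of PAS_chr1-4_0394, on the minus strand of chromosome 1 at 2136313 to 2137797 (ASM2700v1), a single coding exon of 1485 bp. It went from 53.0 ± 14.2 CPM with nitrogen to 3072 ± 171 CPM without (SD, n = 3 each), a log2 fold change of 5.80 ± 0.18 (SE), from 11 to 29 counts per library with nitrogen to between 411 and 1173 without. PAS_chr1-1_0030 followed, on chromosome 1 at 594551 to 596305. It rose from 623 ± 76.6 to 5126 ± 753 CPM, a log2 fold change of 3.04 ± 0.13 (SE).

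The largest falls that met the same rule were at PAS_chr4_0065 (chromosome 4, 129794 to 130816) and PAS_chr4_0240 (chromosome 4, 486364 to 488484). PAS_chr4_0065 went from 257 ± 182 to 57.7 ± 32.9 CPM (SD, n = 3 each), a log2 fold change of -2.35 ± 0.28 (SE; edgeR adjusted p = 1.51e-14). Its libraries with nitrogen ranged from 103.9 to 458 CPM, and its call was lost with DESeq2 (adjusted p = 0.0717) and with edgeR's robust setting (adjusted p = 0.230); over 16 alternatives its adjusted p ran from 8.85e-19 to 0.230. Without replicate 2 with nitrogen its log2 fold change was -1.69, and over the alternatives it ran from -2.71 to -1.69. PAS_chr4_0240 fell from 153 ± 38.2 to 38.0 ± 23.5 CPM, a log2 fold change of -1.85 ± 0.32 (SE; edgeR adjusted p = 5.73e-07), and passed under all 16 alternatives that tested it. PAS_chr4_0240 had 36 to 65 counts per library with nitrogen and 2 to 18 without. PAS_chr4_0065 had 32 to 133 with nitrogen and 10 to 17 without. In CPM its groups were barely apart, at 103.9 in replicate 3 with nitrogen and 95.5 in the shallow replicate 3 without. The stricter filter removed both genes. The table names no function for any of these 4 genes.

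**Figure D1:**
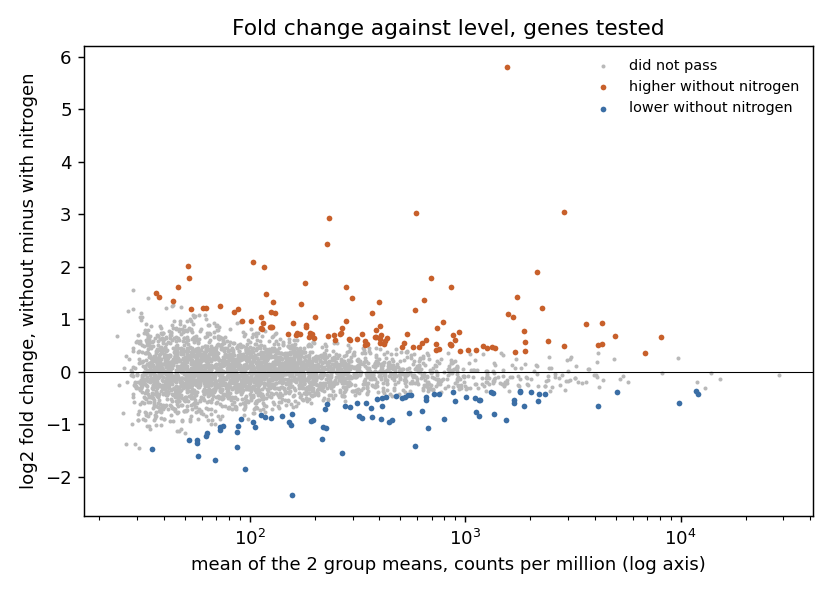
Each point is 1 of the 3330 genes tested. The horizontal axis is the mean of the 2 group means in CPM (log axis) and the vertical axis is the log2 fold change, without minus with nitrogen; orange and blue points are the 122 higher and 89 lower genes at an adjusted p under 0.05, and 1 gene stands above the rest at 5.80.

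The calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 547 genes had an unadjusted p under 0.05. Groups did not overlap for 198 of the 211 called genes, and for 20.2% of all tested genes, where chance gives 10%. DESeq2 called 113 genes, 110 of them among the 211, and leaving out 1 library gave between 129 and 183. The loss exceeded 1.5 times without replicate 2 with nitrogen (132), without replicate 1 (132) and without replicate 2 (129) without nitrogen; without the shallow replicate 3 without nitrogen, 183 genes were called.

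The second question was how the genes of the methanol pathway, whose substrate both groups were given, differed without nitrogen. By total count over all libraries, DAS2, DAS1, AOX1 and FDH1 ranked 1, 4, 5 and 8 among the genes of the table, and the rarest member, FGH1, ranked 427. As a group the genes were lower by camera with the preset correlation (limma, adjusted p = 3.51e-05), but not with an estimated correlation (adjusted p = 0.135 with an estimated correlation). All 9 methanol utilization genes had a log2 fold change below 0, with a median of -0.31 and a range from -0.60 to -0.07. At an adjusted p under 0.05 over all genes, 3 fell, none rose and 6 did not pass; adjusted over the list alone, 6 fell. Together the 9 genes took 8.06% ± 0.482 of all counts with nitrogen and 6.70% ± 0.619 without (SD, n = 3 each). In this unscaled share, every library without nitrogen lay below every library with nitrogen. That gives an exact permutation p of 0.1, the smallest this design allows. The gap was narrow, with 7.40% in replicate 1 without nitrogen and 7.55% in replicate 1 with nitrogen. Their TMM factors were 0.969 and 1.04, and on the TMM scale the order of these libraries turns. The separation therefore depends on the scaling.

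FDH1 (PAS_chr3_0932, chromosome 3, 1821897 to 1822994), the formate dehydrogenase that takes the last step of methanol oxidation to carbon dioxide, fell from 11795 ± 1424 to 7769 ± 771 CPM (SD, n = 3 each), a log2 fold change of -0.60 ± 0.12 (SE; edgeR adjusted p = 5.64e-05). AOX2 (PAS_chr4_0152, chromosome 4, 301802 to 303793), the second alcohol oxidase, fell from 2037 ± 392 to 1348 ± 169 CPM, a log2 fold change of -0.59 ± 0.13 (SE; edgeR adjusted p = 1.69e-04). Both passed under all 17 alternatives.

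AOX1 (PAS_chr4_0821, chromosome 4, 1547751 to 1549742), the main alcohol oxidase, went from 13752 ± 1141 to 10199 ± 2614 CPM, a log2 fold change of -0.43 ± 0.12 (SE; edgeR adjusted p = 0.0139). Its libraries without nitrogen spread from 13060 CPM in replicate 1 to 7939 in replicate 3, and the groups overlapped. The call failed in 5 of 18 alternatives, which include AOX1 and AOX2 counts summed. Over these the adjusted p ran from 2.32e-04 to 0.444, the highest with DESeq2, where the log2 fold change was -0.43. Leaving out replicate 1 without nitrogen gave a log2 fold change of -0.65 and leaving out replicate 3 gave -0.28 (adjusted p = 0.319).

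The other members did not pass over all genes. FLD1, the formaldehyde dehydrogenase (PAS_chr3_1028, chromosome 3, 1980650 to 1981903), had a log2 fold change of -0.36 ± 0.12 (SE; edgeR adjusted p = 0.0523) with groups that did not overlap, and passed in 7 of 17 alternatives. DAS1 (PAS_chr3_0832) and DAK2 (PAS_chr3_0841), the dihydroxyacetone synthase and kinase of formaldehyde assimilation, had -0.31 ± 0.12 and -0.28 ± 0.12; DAS1 passed in 3 of 17 alternatives and DAK2 in none of 17. For DAS2 (PAS_chr3_0834), the second dihydroxyacetone synthase and the gene with the highest total count in the table, the log2 fold change was -0.07 ± 0.12, with a 95% interval from -0.31 to 0.18. CTA1, the peroxisomal catalase (PAS_chr2-2_0131), had -0.13 ± 0.12. It passed in none of 17 alternatives, over which its log2 fold change ran from -0.27 to -0.015. FGH1, the S-formylglutathione hydrolase (PAS_chr3_0867), had -0.07 ± 0.16, and its sign turned without replicate 3 of either group.

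**Figure D2:**
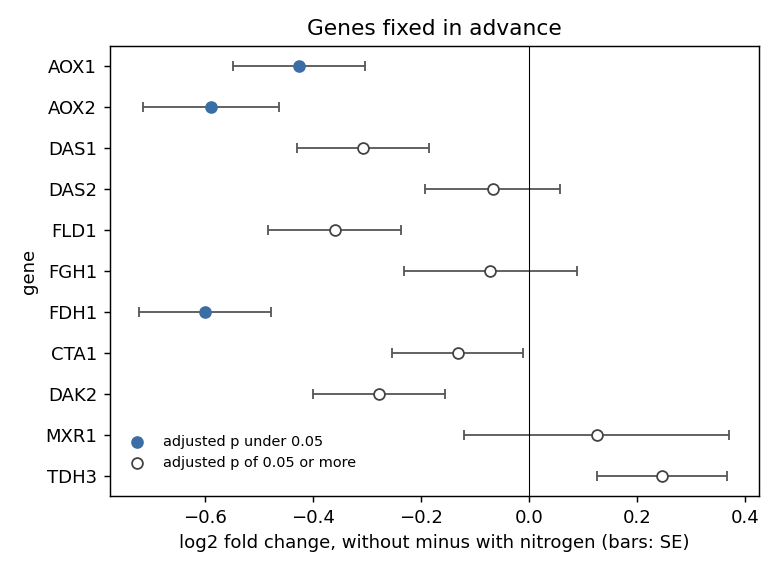
Log2 fold changes, without minus with nitrogen, for the 11 genes named in advance, with bars of 1 SE and n = 3 libraries per group. Filled points (AOX1, AOX2 and FDH1) have an adjusted p under 0.05; all 9 methanol utilization genes lie left of 0, and MXR1 and TDH3 lie right of it without passing.

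Only 1 list could be tested, so adjustment over lists leaves each list p as it is. Fry (limma), which asks whether the list's genes move on balance one way, gave an adjusted p = 0.0499, and did not pass in 8 of 13 alternatives, from 0.0177 to 0.186; it was not run with DESeq2 or limma-voom, and the other edgeR dispersion settings do not enter it.

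AOX1 with AOX2, and DAS1 with DAS2, are closely similar pairs whose reads the authors' counting could have split, so single values of these 4 genes are uncertain. With counts summed, AOX1 and AOX2 together had a log2 fold change of -0.45 ± 0.12 (SE; edgeR adjusted p = 0.00793) and DAS1 and DAS2 together -0.14 ± 0.13 (adjusted p = 0.670). Within libraries, the log2 ratio of DAS1 to DAS2 was -1.04 ± 0.0542 with nitrogen and -1.27 ± 0.0424 without (SD, n = 3 each), without overlap (exact permutation p = 0.1, the smallest possible). The log2 ratio of AOX2 to AOX1 was -2.77 ± 0.172 and -2.90 ± 0.250 (exact permutation p = 0.5).

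**Figure D3:**
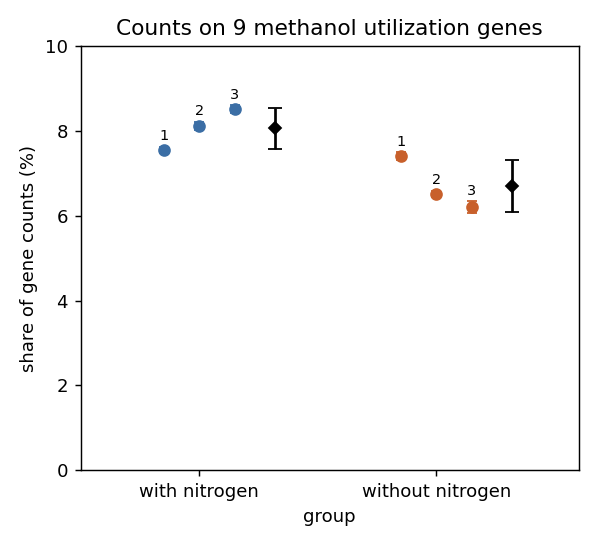
Share of each library's gene counts, in percent, that fell on the 9 methanol utilization genes, by group. Coloured points are libraries, numbered by replicate, with exact 95% intervals for counting error, and black diamonds are group means with SD (n = 3); the libraries without nitrogen lie between 6.20% and 7.40% and those with nitrogen between 7.55% and 8.51%.

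Outside the pathway's enzymes, MXR1 (PAS_chr4_0487, chromosome 4, 956789 to 960256), the transcription factor that activates methanol genes, was at 136 ± 17.0 CPM with nitrogen and 154 ± 36.1 without. Its log2 fold change of 0.12 ± 0.25 (SE; edgeR adjusted p = 0.882) has a 95% interval from -0.36 to 0.61, at 24 to 51 counts per library, so changes within that interval are not excluded. TDH3 (PAS_chr2-1_0437, chromosome 2, 807591 to 808592), the glycolytic glyceraldehyde-3-phosphate dehydrogenase, was at 4516 ± 652 and 5338 ± 792 CPM. Its log2 fold change was 0.25 ± 0.12 (SE, edgeR adjusted p = 0.278). TDH3 passed under none of 17 alternatives, over which the log2 fold change ran from 0.11 to 0.32.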

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

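Thinning, the other edgeR settings and the summed paralogs were chosen after the data were seen. The counts of called genes stayed within 1.5 times of 211 under the other scalings, limma-voom, both filters and the other edgeR settings (169 to 220), and in every one more genes were higher than lower. DESeq2 called 113 (66 higher, 47 lower). With all libraries thinned to 127303 counts, 130 were called (80 and 50), 118 of them among the 211, with 2131 genes tested. By construction, a log2 fold change of at least 1 kept 64 (40 and 24), and glmTreat against 1.5-fold 34 (27 and 7). Leaving out 1 library gave 129 to 183 genes (70 to 105 higher, 48 to 78 lower), with 2 libraries left in an arm. With the replicate block, 168 genes were called, 164 of them among the 211. AOX1 did not pass with it (edgeR adjusted p = 0.104), at a log2 fold change of -0.46 against -0.43 without the block. Deviations of same-numbered libraries from their group means correlated at -0.067, -0.0321 and -0.0579. No library correlated best with its own number, so the numbers are not shown to pair the samples. The methanol list was lower by camera under all 15 alternatives that enter that test (adjusted p over the 1 list from 2.87e-07 to 0.00356; 3.99e-07 to 0.00119 with a library left out), but not with an estimated correlation (adjusted p = 0.135 with an estimated correlation, and 0.0843 to 0.267 over the 13 alternatives in which it was run, without DESeq2 and limma-voom). The difference in its share of counts ran from -1.70 to -1.11 percentage points with a library left out, that of the log2 ratio of DAS1 to DAS2 from -0.27 to -0.22, and that of AOX2 to AOX1 from -0.27 to -0.03. Of 254 values of named genes under alternatives, including the summed AOX and DAS pairs, 235 kept direction and side of the threshold. Of the rest, 7 lost the call, 10 gained it, and 2 turned sign, both of FGH1. With a library left out FGH1 ran from -0.25 to 0.059. It lay above 0 without replicate 3 with nitrogen and, at 0.0082, without replicate 3 without nitrogen. The causes were not tested. The first component kept the groups apart with a prior count of 0.5, the 500 most variable genes, and thinning (36.9% to 46.8% of the variance). In the main setting, replicates 1 and 2 without nitrogen lay at 1.78 and 3.43 on it and the shallow replicate 3 at 26.9. Its share of the variance therefore does not measure the group difference alone. With the real library sizes and number of replicates, and edgeR's estimated spreads, 34.0% of simulated 1.5-fold changes were called. How much of this is due to depth was not tested.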

Other observations

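The tests on neighbouring genes, called genes side by side, introns, chromosome ends and chromosomes were chosen after results had been seen, and the other tests were written after a first fit of these data but before their own values. Called genes were spread over all 4 chromosomes, with 7.13% of tested genes called on chromosome 1, 5.26% on chromosome 2, 4.99% on chromosome 3 and 8.23% on chromosome 4. None of the chromosomes differed from the rest in direction by camera (adjusted p = 0.998 for each over 6 groups). Of 384 tested genes with an intron in the coding sequence, 15 were higher and 10 lower, with a median log2 fold change of -0.01 (limma's camera, adjusted p = 0.998 over 6 groups). Another group held the 116 tested genes within 50 kb of the start of a chromosome's sequence or of its last annotated gene end. Of these, 7 were higher and 2 lower, with a median log2 fold change of 0.06 (limma's camera, adjusted p = 0.998 over 6 groups). Neither result excludes a small shift. The share of called genes did not pass for any of the 6 groups (Fisher's exact test, two-sided, lowest p = 0.0308, for chromosome 4, adjusted p = 0.185). Called genes lay side by side in 11 pairs, 8 of them in the same direction, against a mean of 8.94 in 10000 random placements (permutation p = 0.284, one-sided).

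Neighbouring genes that point at each other had correlated fold changes. Only pairs with both genes tested and no overlap of their coding regions entered, so overlapping neighbours are not covered by the tests below. Over 575 convergent pairs Spearman's rho was 0.158 and Pearson's r 0.119 (adjusted p = 3e-04, from the smallest p that 10000 permutations can give), over 1019 tandem pairs rho was 0.0999 and r 0.0979 (adjusted p = 0.0027), and over 625 divergent pairs rho was 0.0611 and r 0.0476 (adjusted p = 0.128); these are correlations across gene pairs, which are not independent replicates. A candidate explanation is that 3' end reads were counted for the neighbour, since convergent genes lie a median of 85 bp apart. Pairs up to 100 bp apart then should correlate more than pairs further apart, but the difference in rho was 0.00954 (0.162 against 0.152, permutation p = 0.909), which neither shows nor excludes it. Co-regulation of a region whatever the orientation also stays open, since the difference of 0.0968 between convergent and divergent pairs did not pass (permutation p = 0.096).

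Replicate 3 without nitrogen lay far from its group, and its low total is a candidate explanation. Its mean distance to the other 2 libraries of its group, divided by the distance between those 2, was 1.39 at full depth. After all libraries were thinned to its total, the ratio was 1.07, from 1.03 to 1.12 over 20 draws, on both sides of the bound, which was set before this ratio was computed but after a first fit of these data had been seen. Thinning adds counting noise to every distance and so pulls the ratio toward 1 whatever the cause. Depth and a difference of the culture therefore cannot be told apart with this one library. No biological explanation was tested.

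The lower methanol utilization genes could follow from a few strongly risen genes taking up counts. With all 122 higher genes left out of the counts and the scaling, the list's median log2 fold change was -0.286, against -0.308 with them. It ran from -0.374 to -0.231 with a library left out. TMM already limits the weight of strongly risen genes, so this median could hardly move, and the test does not decide. The list's share of counts, which TMM does not enter, was not recomputed without those genes. They took a mean of 7.26% of counts with nitrogen and 12.8% without. Leaving them out of the total would therefore raise the list's share more without nitrogen. The fall in share would narrow, and the groups would overlap. Correlated spread among the pathway's genes stays open: the estimated inter-gene correlation was 0.54, and the list's camera adjusted p was 0.135 with it. An effect of nitrogen on the pathway is the design's own explanation and was not tested further. For the count of called genes, the real split of the 6 libraries gave 211 genes. It was the only 1 of 10 splits to give as many, the highest other split giving 1. Every other split mixes both groups on each side, so a real difference would add to its spread and lower its calls. Besides, 10 splits are too few for a share under 0.05.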
